A study of Rattus norvegicus with 10 samples.

How the data were processed

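Total RNA from the cavernosal tissue of the penis of F344 rats, an inbred strain, was measured on Affymetrix RAE230A arrays, with 1 array per sample. Per the labels, 5 samples came from control rats and 5 from rats made diabetic with streptozotocin, a toxin of pancreatic beta cells, and taken at 10 weeks. Replicate numbers 1 to 5 follow the order of deposit and pair nothing. No label says more than that the samples are separate, so the p-values measure the spread between these samples.

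The deposited table holds 1 linear intensity per probe set and array. The authors' values range up to 13504.7, and the mean of each array without the lowest and highest 2% of its values lies between 249.951 and 250.26, so each array had been scaled to a common trimmed mean. The software behind the intensities is not given in the sources used here, and the table holds no detection calls, so no probe set could be said to lie below background. Per the file headers of the array records, all 10 arrays came from 1 chip lot, were scanned on 4 days and were washed on 2 fluidics stations. Scan day 1 held controls 1 and 5 and diabetic 2, and these arrays had a different operator from the rest. Day 2 held control 4 and diabetic 1, day 3 held controls 2 and 3 and diabetics 4 and 5, and day 4 held diabetic 3 alone. Station 1 held 4 controls and 1 diabetic array, and station 2 held 1 control and 4 diabetic arrays, so station and group were partly confounded.

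Of 15923 rows, 57 control probe sets were left out. Among the remaining 15866, the platform annotation named 1 gene for 12783, several for 312 and none for 2771. Symbols were updated through the Entrez identifier for 12748 of the 12783. Values below 1 were set to 1, and log2(intensity + 16) was taken, so a fold change is on that scale and understates changes of dim probe sets. The largest difference between array medians was 0.15 on the log2 scale, under the limit of 0.5 set for further scaling, and the values were used as deposited. A probe set was tested if at least 5 of the 10 arrays exceeded the 40th percentile of the table, an intensity of 85.9, which left 9683 probe sets, 8213 of them with 1 gene, and 7143 genes.

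Diabetic and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. There were 35 gene lists, 24 of pathways and 11 of cell type markers, and a list was tested if it had at least 5 tested genes, each read by its brightest probe set. Lists were tested against all other genes with limma's camera, at a preset inter-gene correlation of 0.01. A second test took the array as the unit: an exact permutation test of the list mean per array over all 252 assignments, two-sided, whose smallest possible p is 0.00794. Both were adjusted over the 32 lists tested. A panel of 14 genes often discussed in diabetic erectile dysfunction was adjusted over all probe sets and over the panel alone. The genes named were, among called probe sets with 1 gene and no overlap between the groups, the 12 higher and the 12 lower with the largest change, 1 probe set per gene. To these were added the panel and up to 4 members per list with the smallest unadjusted p. The groups, tests, lists, naming rule and the first set of alternatives were fixed before the data were examined. A gene outside this rule is said to have been chosen after its values were seen.

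The fit was tested on simulated data for this comparison, with 9683 probe sets, 200 of them changed, in 20 simulations with 5 arrays per group. It called 79.8% of the 2-fold and 96.0% of the 4-fold changes, and 5.26% of its calls were false. The simulated noise was independent between probe sets and equally wide in both groups. In the data, control arrays varied more than diabetic arrays, with pairs correlating down to 0.774 against 0.956. These rates therefore need not hold for these samples. Camera called a list of 25 genes shifted by 0.5 in 100% of simulations and 0.5% of unshifted lists, whose genes were simulated without correlation. Alternatives set at that time covered quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, and scan day and station as blocks. They further covered eBayes without a trend, array weights, stricter thresholds, an estimated inter-gene correlation, fry, the mean of all probe sets per gene, and each array left out in turn. A further 5 alternatives, chosen after seeing the data, used the epithelial or skeletal muscle list mean as a covariate or left out sets of control arrays. Figures were drawn with matplotlib 3.10.9.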

Results

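The study measured gene expression in cavernosal tissue of 5 control and 5 streptozotocin-diabetic rats, the erectile tissue of the penis, and its design asks which transcripts differ in diabetes. Median intensities of the 10 arrays lay between 116.8 and 131.4, and the number of arrays limits the precision. Across tested probe sets, pairs of diabetic arrays correlated at 0.956 to 0.972, whereas pairs of control arrays ranged from 0.774 to 0.974, a correlation across probe sets, which are not independent replicates. The first principal component held 61.5% of the variance and did not separate the groups (exact permutation p = 0.151), and the second held 11.5% (exact permutation p = 0.0159).

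Among single genes, Myh8, Pdk4 and Lpl rose in diabetic tissue, and G0s2 and Col1a1 fell. Myh8, the perinatal skeletal myosin heavy chain, rose 6.71-fold, from an intensity of 356.2 ± 205 to 2399 ± 1392 (SD, n = 5 per group), a log2 change of 2.75 ± 0.43 (SE; limma adjusted p = 0.0372). Pdk4, the kinase that restrains pyruvate oxidation, rose 5.17-fold (log2 2.37 ± 0.34, adjusted p = 0.0372), and Lpl, lipoprotein lipase, rose 2.66-fold (log2 1.41 ± 0.15) with the smallest adjusted p of all, 0.0108. G0s2, an inhibitor of adipose triglyceride lipase, fell by 2.65 ± 0.41 on the log2 scale (adjusted p = 0.0372). Col1a1, a chain of type I collagen, fell by 2.36 ± 0.41 by one of its probe sets, from 3598 ± 838 to 810.9 ± 526 (adjusted p = 0.0490).

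In all, limma called 41 of 9683 probe sets, 21 higher and 20 lower, for 18 higher and 16 lower named genes, and 26 of the 41 changed at least 2-fold. In all 41 the 5 diabetic and 5 control values did not overlap. Such separation held for 377 of the 9683 probe sets (3.89%, against 0.794% by chance). The remaining genes with the largest increases were Impa2, an inositol monophosphatase (1.53 ± 0.26), Cp, the copper-carrying ferroxidase ceruloplasmin (1.52 ± 0.24), and Sln, sarcolipin, an inhibitor of the muscle calcium pump (1.51 ± 0.22). Smaller increases were those of Rasgef1b (1.38 ± 0.25), B4galt1, a galactosyltransferase (1.25 ± 0.15), Cidea, a lipid droplet protein (1.15 ± 0.19), Agpat2, an acyltransferase of triglyceride synthesis (1.07 ± 0.13) and Slc39a8, a zinc transporter (1.07 ± 0.17). Decr1, an enzyme of fatty acid oxidation, rose from an intensity of 399.3 ± 94.2 to 813.3 ± 182 (SD). Decreases were seen for Grem1, a BMP antagonist (-2.15 ± 0.39), Mrln, myoregulin, another inhibitor of the muscle calcium pump (-1.83 ± 0.33), the matrix protein Sparc (-1.46 ± 0.24), and Tfrc, the transferrin receptor (-1.44 ± 0.23). The others were Nrep (-1.32 ± 0.23), Gpcpd1 (-1.30 ± 0.24), Lox, the enzyme that crosslinks collagen and elastin (-1.20 ± 0.19), Slc41a3 (-1.07 ± 0.16), Dpp4, a peptidase (-0.95 ± 0.15), and Tp53inp2 (-0.84 ± 0.14). Except for Decr1, these are log2 changes with limma SE. Adjusted p of the 24 genes lay between 0.0108 and 0.0497.

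**Figure D1:**
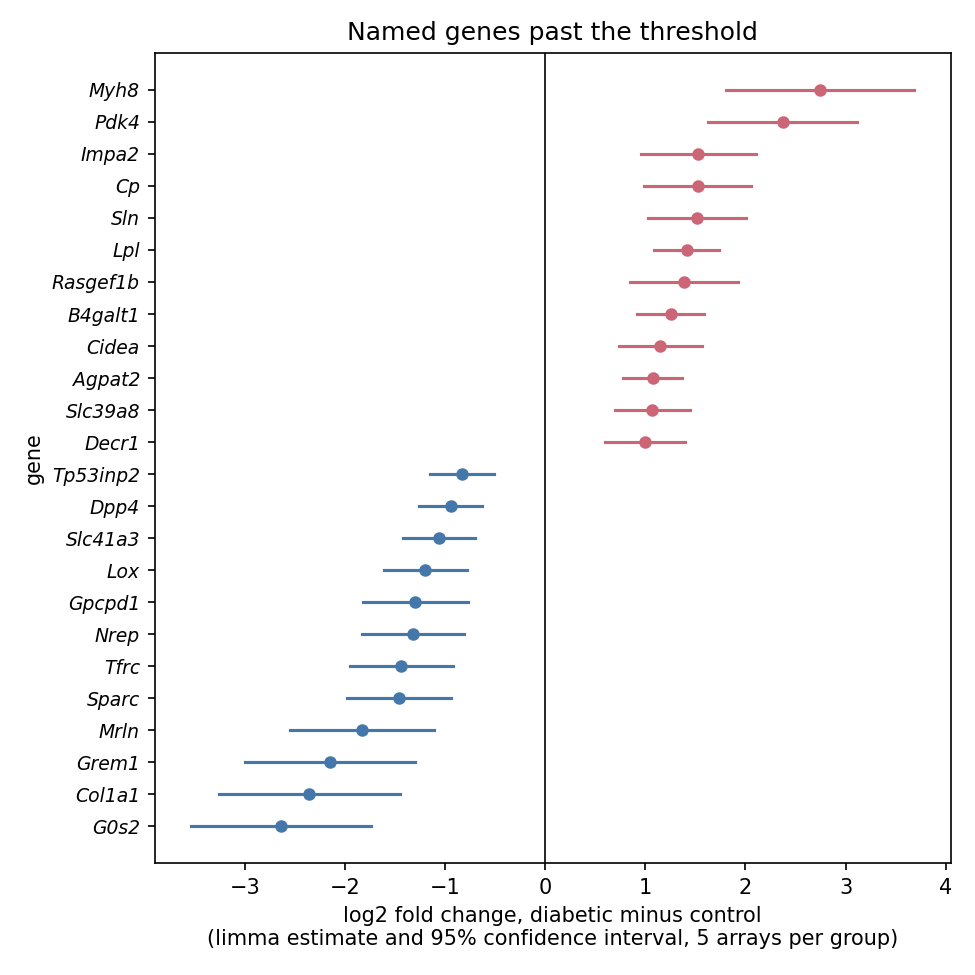
Log2 fold change (diabetic minus control, horizontal axis) of the 24 named genes past the threshold, with points for the limma estimate and lines for its 95% confidence interval, over 5 arrays per group. Myh8 (2.75) stands highest and G0s2 (-2.65) lowest.

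Since the values of the 24 named genes do not overlap between the groups, their sign within a scan day or station was fixed, and only the size could vary. Myh8 lay higher by 2.45, 2.87 and 2.70 within scan days 1, 2 and 3, and by 2.42 and 1.86 within stations 1 and 2. Col1a1 lay at -1.64, -2.77 and -1.95 and at -1.81 and -2.07. With scan day as a block Myh8 stood at 2.66 (adjusted p = 0.128) and Lpl at 1.36 (adjusted p = 0.123). With station as a block they stood at 2.14 (adjusted p = 0.192) and 1.38 (adjusted p = 0.162). In either fit limma called 0 probe sets, with 1119 and 1483 at an unadjusted p under 0.05 against 1695 without a block. Diabetic 3, alone on scan day 4, adds nothing to the group difference in the scan day fit, and either block costs precision. The loss of calls therefore need not mean an effect of scan day or station. Leaving out single arrays gave 0 calls without control 1, 1 without control 2, 24 without control 3, 8 without control 4 and 1068 without control 5, and 2, 0, 0, 13 and 6 without diabetic 1 to 5. Median centring turned the share of higher calls from 51.2% of 41 to 29.55% of 44, quantile normalization called 49 (44.9% higher), and array weights called 2813.

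The control samples differed among themselves in epithelial genes. The epithelial list, of keratins, claudins and other genes of lining and gland cells, averaged 5.78 in control 1, 5.78 in control 2, 9.14 in control 3, 7.51 in control 4 and 9.59 in control 5 (mean log2 intensity of 14 genes), and 8.55 to 9.67 in the 5 diabetic arrays. Genes of secretory glands, chosen after their values were seen, followed it in part. Pip read 8.8 in control 1, 988.6 in control 2 and 1312 to 8140 in the other controls, against 5774 to 7429 in diabetic arrays. Pigr, the receptor that carries antibodies across epithelium, read 53.9 and 121.8 in controls 1 and 2 and 1134 to 5844 in the others. Without controls 1 and 2, an alternative chosen after seeing the data, limma called 0 probe sets, with 773 at an unadjusted p under 0.05, and without controls 1, 2 and 4 it called 21, of which 6 were among the 41. With the epithelial list mean as a covariate it called 19, 10 of them among the 41, and with the skeletal muscle list mean 0, with 628 at an unadjusted p under 0.05. With the skeletal muscle covariate Myh8 stood at 2.98 ± 0.59, Pdk4 at 2.74 ± 0.44, Lpl at 1.24 ± 0.19 and Col1a1 at -1.92 ± 0.54, against 2.75 ± 0.43, 2.37 ± 0.34, 1.41 ± 0.15 and -2.36 ± 0.41 without it. Mrln (-0.94 ± 0.19), Cp (0.95 ± 0.20) and Rasgef1b (0.75 ± 0.18) lay nearer to 0 than without it, where they stood at -1.83 ± 0.33, 1.52 ± 0.24 and 1.38 ± 0.25.

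**Figure D2:**
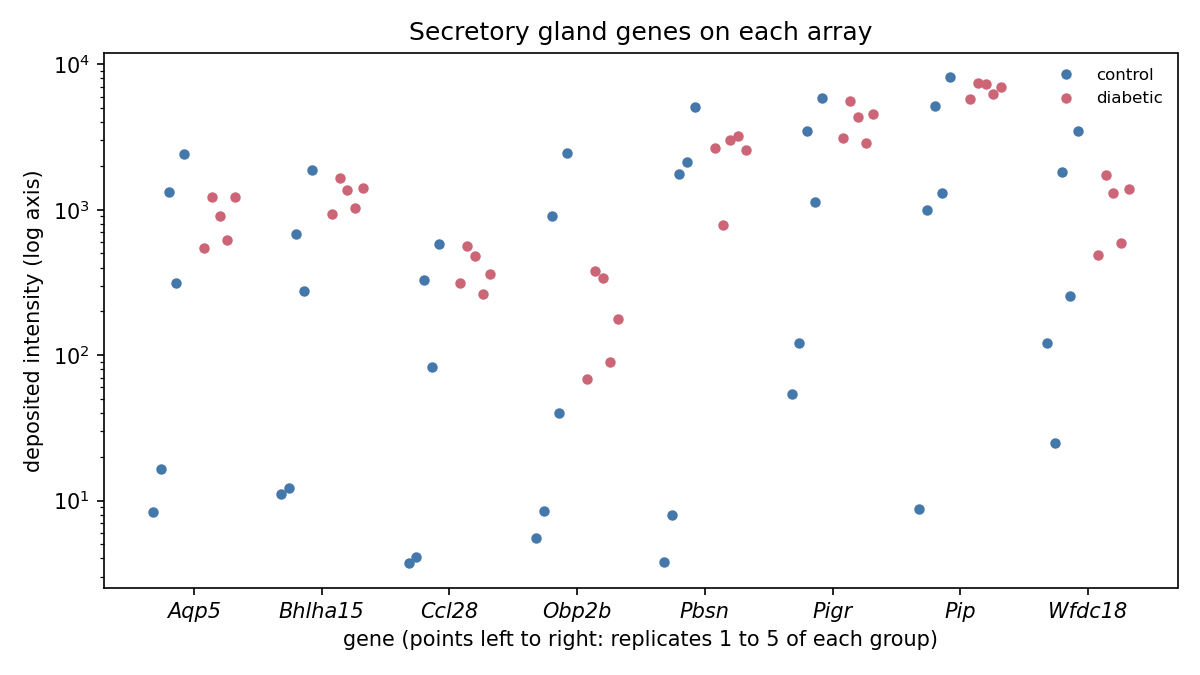
Deposited intensity (vertical log axis) of 8 secretory gland genes on each array, with control arrays in blue and diabetic arrays in red, replicates 1 to 5 from left to right within each gene and group. Controls 1 and 2 lie far below most other arrays, for example at 53.9 and 121.8 for Pigr against 5844 in control 5.

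Among the gene lists, collagen and elastic matrix genes lay lower in diabetic tissue and fatty acid oxidation genes higher. The 35 matrix genes averaged -0.55 on the log2 scale, with 31 of 35 negative (camera adjusted p = 3.88e-11; adjusted p = 0.481 with an estimated correlation). Lox alone passed over all genes, and 14 members fell adjusted over the list alone, among them Col1a2 (-1.81 ± 0.36), Col3a1 (-1.35 ± 0.27) and the brighter Col1a1 probe set (-2.05 ± 0.43, adjusted p = 0.0658 over all). Sparc, too, passed by one probe set while the brighter one, at -1.19 ± 0.27, did not (adjusted p = 0.0770). The 25 genes of fatty acid oxidation and ketone use averaged 0.61, with 21 of 25 positive (adjusted p = 3.96e-07; adjusted p = 0.481 with an estimated correlation). Pdk4, Acaa2 (0.77 ± 0.13) and Decr1 passed over all genes, and adjusted over the list alone 13 rose and 1, the ketone-using enzyme Oxct1 (-0.36 ± 0.10), fell. Acadl, the long-chain acyl-CoA dehydrogenase, stood at 0.86 ± 0.16 (adjusted p = 0.0526 over all). The matrix list stood at -0.50 and the fatty acid list at 0.60 with scan day as a block. They stood at -0.53 and 0.51 with station as a block, and at -0.29 and 0.71 with the epithelial covariate. Within scan days 1, 2 and 3 the matrix list stood at -0.36, -0.68 and -0.50 and the fatty acid list at 0.58, 0.86 and 0.48, and within stations 1 and 2 at -0.49 and -0.57, and at 0.53 and 0.49.

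Skeletal muscle markers lay lower as a group, by a small margin. They averaged -0.29, with 20 of 21 negative (camera adjusted p = 9.77e-05; adjusted p = 0.481 with an estimated correlation), and 0 passed over all genes. Adjusted over the list alone, Casq1, the calcium-storing protein calsequestrin, fell (-0.64 ± 0.16), while Pvalb, the calcium buffer parvalbumin, stood at -1.79 ± 0.55 without passing. These markers were bright in all samples, with Actn3 at 11246 ± 1307 in control and 8442 ± 2185 in diabetic arrays. Of the 50 brightest probe sets, 9 named one, against 2 that named a gene of the smooth muscle list. The samples thus carried strong skeletal muscle signal, and a change in them need not be one of the erectile tissue itself. Oxidative phosphorylation averaged -0.25, with 28 of 32 negative, 0 passing either way and Ndufb5 at -0.56 ± 0.14 (adjusted p = 8.55e-07; adjusted p = 0.575 with an estimated correlation). Proteasome genes averaged -0.17, with 12 of 15 negative and 0 passing either way (adjusted p = 0.00151; adjusted p = 0.575 with an estimated correlation). Glycolysis averaged -0.18, with 13 of 20 negative (adjusted p = 0.0298; adjusted p = 0.481 with an estimated correlation). None of its members passed over all genes, while adjusted over the list alone Ldha, lactate dehydrogenase (-0.57 ± 0.14), and Akr1b1, aldose reductase (-0.68 ± 0.21), fell and Aldoc rose (0.66 ± 0.20). With scan day as a block these 4 lists stood at -0.33, -0.27, -0.18 and -0.19, and with station as a block at -0.36, -0.33, -0.25 and -0.24. Within scan days 1, 2 and 3 skeletal muscle stood at -0.44, -0.40 and -0.22, and oxidative phosphorylation at -0.39, -0.058 and -0.29. The proteasome list stood at -0.27, -0.15 and -0.15 and glycolysis at -0.27, -0.28 and -0.083. Within stations 1 and 2 the 4 lists stood at -0.52 and -0.20, -0.46 and -0.19, -0.30 and -0.20, and -0.29 and -0.20. With the epithelial covariate oxidative phosphorylation stood at -0.043 (adjusted p = 0.114) and the proteasome list at 0.0079 (adjusted p = 0.397). These lists lost their call with the skeletal muscle covariate as well, at -0.030 (adjusted p = 0.217) and 0.013 (0.438), and without controls 1, 2 and 4, at -0.025 (0.358) and 0.013 (0.650). Glycolysis lost its call while its mean stayed near that reported without control 5 (-0.20, adjusted p = 0.123), without diabetic 1 (-0.16, 0.0714), with quantile normalization (-0.14, 0.215) and with fry (0.0862), and while it lay further from 0 with median centring (-0.25, 0.103) and without controls 3 and 5 (-0.23, 0.147). It also lost the call, with a mean nearer to 0, with the skeletal muscle covariate (-0.060, 0.298) and without controls 1, 2 and 4 (-0.10, 0.0782).

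Epithelial markers averaged 1.68, higher for 14 of 14 genes, with 0 passing over all genes or over the list alone (camera adjusted p = 9.77e-05; adjusted p = 0.663 with an estimated correlation). Dsp, desmoplakin, stood at 1.40 ± 0.55 and Krt5 at 1.11 ± 0.42, and the list stood at -0.12 without controls 1, 2 and 4 and at 0.15 with the skeletal muscle covariate (adjusted p = 0.899). Adipocyte markers averaged 0.60 over 5 genes (adjusted p = 0.0101; adjusted p = 0.481 with an estimated correlation), of which Lpl and Cidea passed over all genes and Lipe, hormone-sensitive lipase (0.60 ± 0.19), adjusted over the list alone, while Cfd (-0.56 ± 0.42) and Fabp4 (0.38 ± 0.38) did not. Without the intensity filter the adipocyte list averaged 0.32 (adjusted p = 0.0196). Its call ended without control 5 (0.43, adjusted p = 0.160) and without controls 3 and 5 (0.34, adjusted p = 0.390). Glucocorticoid-responsive genes averaged 0.50, with 15 of 15 positive (adjusted p = 0.0137; adjusted p = 0.801 with an estimated correlation). Pdk4 passed over all genes, and Angptl4 (1.70 ± 0.33) and Glul, glutamine synthetase (0.41 ± 0.11), adjusted over the list alone. Pdk4 and Angptl4 also belong to the fatty acid list. Control 3 decided this call, since without it the list averaged 0.27 (adjusted p = 0.519), and it ended with station as a block (0.38, adjusted p = 0.197). It also ended with the skeletal muscle covariate (0.44, adjusted p = 0.0623) and without controls 3 and 5 (0.22, adjusted p = 0.770). With scan day as a block the epithelial, adipocyte and glucocorticoid lists stood at 1.64, 0.59 and 0.51, and with station as a block the first 2 stood at 1.86 and 0.57. Within scan days 1, 2 and 3 they stood at 1.98, 2.03 and 1.22, at 0.75, 0.96 and 0.30, and at 0.49, 0.19 and 0.67. Within stations 1 and 2 the epithelial list stood at 2.09 and 1.62, the adipocyte list at 0.58 and 0.57, and the glucocorticoid list at 0.68 and only 0.071.

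**Figure D3:**
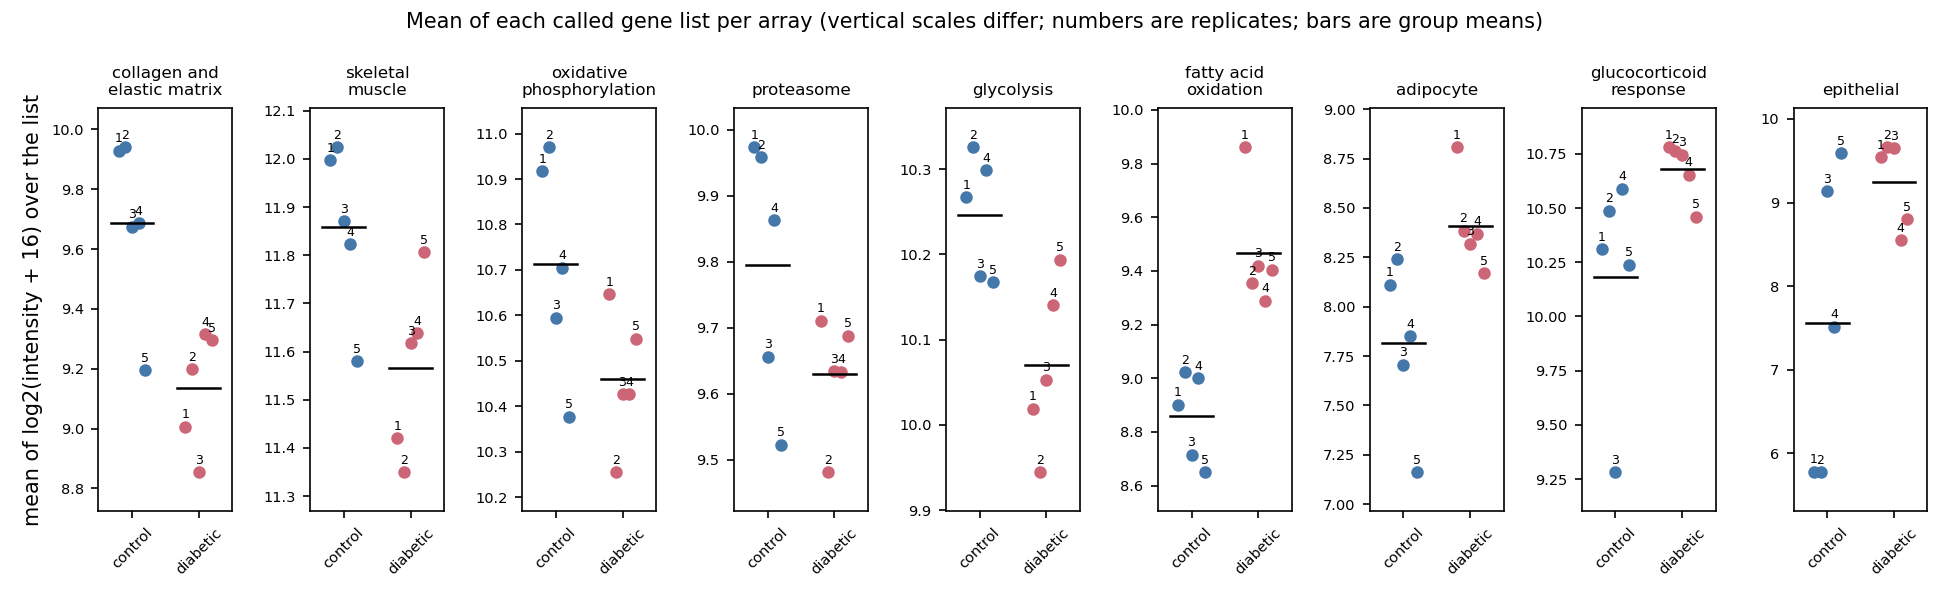
Mean log2(intensity + 16) of the 9 lists called by camera (vertical axes, with a scale per list) on each control (blue) and diabetic (red) array, numbered by replicate, with bars for group means. The fatty acid list separates the groups, at 8.65 to 9.02 against 9.29 to 9.86, while the epithelial list spreads from 5.78 to 9.59 within controls.

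With the array as the unit, 0 of the 32 lists passed the exact permutation test after adjustment, and the smallest adjusted p was 0.127. In this design, lists at the smallest possible p pass only if at least 6 lists reach it, or if many more lie close to it. Camera called at least 9 lists in 54 of 100 splits of the 10 arrays into 5 and 5, the real one included, so its 9 calls are no more than such splits give. Fatty acid oxidation and the acute phase and complement list (0.53 over 9 genes) had the smallest p possible, 0.00794, so each of these 2 list means separated all 5 diabetic from all 5 control arrays. The acute phase list includes Pigr, one of the secretory gland genes above, at 2.42, while the median change of the list was 0.18. Whether this list separates the groups without Pigr was not tested. In the acute phase list Cp passed over all genes, and adjusted over the list alone C3 (0.88 ± 0.17) rose as well and Serpina3n (-0.38 ± 0.10) fell, while camera did not call the list (adjusted p = 0.315).

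The other 22 tested lists were not called by camera, with adjusted p between 0.271 for apoptosis and 0.931 for the circadian clock. Smooth muscle contractile genes averaged 0.13, with Acta2 at 0.30 ± 0.14 and Actg2 at 0.53 ± 0.21, and Tpm1 (-0.40 ± 0.11) fell adjusted over the list alone by its brightest probe set, while the 4 probe sets of Tpm1 differed in sign. Nitric oxide and cGMP genes averaged 0.25, contractile signalling 0.059, endothelial markers 0.051, angiogenic factors -0.071, matrix turnover -0.18 and the TGF, BMP, hedgehog and Wnt list -0.094. With single arrays left out, endothelial markers ran from -0.061 to 0.13 and angiogenic factors from -0.13 to -0.013. Contractile signalling then ran from 0.021 to 0.088 and matrix turnover from -0.29 to -0.10. Adjusted over the lists alone, Cldn5 rose (0.83 ± 0.19) and Plvap fell (-0.86 ± 0.26) among endothelial markers, Ctsk fell in matrix turnover (-1.32 ± 0.32), and Tgfb3 (-0.48 ± 0.11) and Sfrp4 (-0.91 ± 0.25) fell in the TGF list. The androgen list averaged 0.11, apoptosis 0.25, macrophage markers 0.10, cytokines and adhesion molecules 0.084, immediate-early genes 0.22, the stress and heat shock list 0.26, blood cell markers -0.11, proliferation -0.0086 and ribosomal proteins 0.046, with 0 members passing either way. Several of these means hung on single arrays: without one array the cytokine list ran from -0.31 (without control 3) to 0.31 (without control 2), blood cell markers from -0.46 to 0.34 without the same arrays, and immediate-early genes from -0.096 (without control 3) to 0.35 (without control 4). Macrophage markers ran from 0.033 (without diabetic 4) to 0.20 without control 2, where camera called them (adjusted p = 0.0325). Over all alternatives their mean ran from -0.027 to 0.34, and 5 of these settings called them. Quantile normalization led to calls of the stress and heat shock list (0.31, adjusted p = 0.0291) and of ribosomal proteins (0.15, adjusted p = 0.00691), and station as a block to a call of ribosomal proteins (0.18, adjusted p = 0.0414). Lymphocyte, mast cell and cartilage markers had fewer than 5 tested genes and were not tested as lists.

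The panel of 14 genes held 1 call over all probe sets, Cp, and 3 further calls adjusted over the panel alone. These were Col3a1 (fell by 1.35, limma adjusted p = 0.00192 over the panel), the brighter Col1a1 probe set (fell by 2.05, 0.00202) and the smooth muscle myosin Myh11 (rose by 0.52 ± 0.19, 0.0485, against 0.216 over all). Not passing were Eln, elastin (-0.49 ± 0.20), Igf1 (-0.47 ± 0.20), Vegfa (-0.33 ± 0.21), Smtn (-0.16 ± 0.20), Acta2 (0.30 ± 0.14) and Pde5a, the phosphodiesterase that degrades cGMP (0.27 ± 0.20). Nos1, Nos3, Shh and Tgfb1 were on the array but too dim to be tested. With scan day or station as a block the panel held 0 calls, and Cp stood at 1.58 (adjusted p = 0.155) and 1.79 (adjusted p = 0.192).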

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

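Among 65 list means and named genes, tested in both groups for an array far from the other 4, 6 of the 130 tests marked one, where chance alone would mark about 6.5. All values are on the log2(intensity + 16) scale, and no test was made of why any of them stood apart. Control 3 was lowest for the immediate-early list, of genes switched on within minutes of a stimulus, at 8.52 against 9.85 to 10.33 in the other controls. It was also lowest for the glucocorticoid list, at 9.28 against 10.24 to 10.59, and the lists share Dusp1. Diabetic 1 was highest for fatty acid oxidation, at 9.86 against 9.29 to 9.42 in the other diabetic arrays. Control 2 was highest for the proliferation list, at 7.71 against 7.13 to 7.28. Cidea was highest in control 4, at 7.62 against 6.92 to 7.12, and Pde5a in diabetic 4, at 7.71 against 6.92 to 7.10.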

How the results depend on the processing

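All covariates and left-out sets of control arrays here were chosen after seeing the data, and the cause of a change was not tested unless named. The values of all 41 called probe sets do not overlap between the groups, so leaving out arrays could not turn their sign. Their number did not hold. It was 22 with a pseudocount of 1, 26 without a filter, 2813 with array weights, 0 at an adjusted p under 0.01, 0 with scan day or station as a block, and 0 to 1068 without single arrays. It was 19 with the epithelial covariate, 0 with the skeletal muscle covariate, 0 without controls 1 and 2, and 21 without controls 1, 2 and 4. Without controls 3 and 5, the controls nearest the diabetic arrays in epithelial genes, it was 3436, with all 41 included, a number that leaving out such arrays by its construction favours. The total of lists called by camera, 9 in the comparison as reported, was 7 to 10 without single arrays, 15 with the epithelial and 5 with the skeletal muscle covariate, 14 without controls 1 and 2, 14 without controls 1, 2 and 4, and 0 with an estimated correlation. Fry, which tests a list against no change and not against other genes, called 0. Adjusted p of these 9 lists ran from 0.481 to 0.801 with an estimated correlation and from 0.0587 to 0.339 with fry. The exact test called 0 lists in every setting run, where the design left little room for another number. With all 10 arrays, at least 6 lists must reach its smallest p, or many more lie close to it. Blocks and left-out arrays leave fewer assignments still, and the exact test was not run with a covariate. The panel's 1 call became 7 with array weights, 0 with either block or covariate, 0 without controls 1 and 2 and without controls 1, 2 and 4, 7 without controls 3 and 5, and 0 to 5 without single arrays. Blood cell markers turned to 0.77 with the epithelial covariate and 0.64 without controls 1 and 2, epithelial markers to -0.12 without controls 1, 2 and 4, and cytokines to -0.63 without controls 3 and 5. In other settings the cytokine list reached up to 1.15, and 3 settings called it in its reported direction. Over all settings, the 9 called lists kept their call in 192 of 231 cases, lost it in 38 and turned in 1, and the 24 called genes kept it in 261 of 596 cases, lost it in 335 and turned in 0. A sign change in a result called in neither setting was counted as no change. The deposited table gives no background level, so how dim a change it could show is open.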

Other observations

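The splits of the arrays and the list of genes raised in muscle without nerve supply were written down before their results were seen, and the other tests in this part were chosen after. Clock genes, insulin signalling and antioxidant defence held changes that passed only adjusted over the list alone. Per2 (0.66 ± 0.19, SE) and Tef (0.39 ± 0.12) rose and Bmal1 fell by 0.79 ± 0.23 on the log2 scale, while the 13 clock genes averaged -0.014 with a median of 0.14 and a camera direction of up. The hour of sampling is not given in the sources used here. The insulin receptor Insr (0.58 ± 0.13) and Igfbp3, from an intensity of 337.0 ± 125 to 688.7 ± 248 (SD), rose in the insulin and IGF list, which averaged 0.16 over 15 genes. In the antioxidant list, 0.092 over 28 genes, 4 rose and 2 fell, among them Gstm2 (0.85 ± 0.21), Cat, catalase (0.79 ± 0.23), and Nqo1 (0.38 ± 0.12) higher and Mt3 (-0.75 ± 0.20) lower. Schwann cell and nerve markers averaged 0.029 with a median of -0.18 and a camera direction of down, and Erbb3 rose (0.72 ± 0.15). Sox10, another member, had one of the largest weights on the first principal component (0.047), near the epithelial genes Krt15 (0.051) and Cldn4 (0.050). The list may therefore not read nerve alone in these samples. Cholesterol synthesis averaged 0.025 with a median of -0.0077, a camera direction of down and 0 members passing.

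Other splits of the 10 arrays into 5 and 5 were fitted the same way. Of 100 splits, the real one and others drawn at random, 3 called as many probe sets as the real 41, fewer than the 5 set in advance as the limit for chance. The highest other split called 976. That split set controls 1, 2 and 4 and diabetics 1 and 4 against the rest, a structure of the samples that crosses the groups. These arrays lay lowest on the first principal component, at -50.3, -47.2, -26.1, 9.50 and 4.38 in that order. Its largest weights included gland and epithelial genes such as Pbsn (0.080), Pip (0.073) and Epcam (0.069). The remaining split with as many calls, at 238, also kept controls 1, 2 and 4 together. The count thus cannot tell diabetes apart from the makeup of these samples. For camera's list calls chance cannot be excluded, since 54 of the 100 splits called as many as the real 9, with a median of 9 and a maximum of 18 among the others. The split by fluidics station called 11 lists and the split of scan days 1 and 2 against 3 and 4 called 9, both with 0 probe sets. The diabetic comparison with station or scan day as a block likewise called 9 lists and 0 probe sets in either fit.

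Epithelial marker genes differed several-fold between control arrays. Controls 1 and 5 were scanned on 1 day and washed on 1 station, yet their epithelial means differed by 3.81 on the log2 scale, against an SD of 0.53 among diabetic arrays, which argues against scan day or station as the whole cause. The 14 markers moved together, with a median pairwise correlation of 0.933 after group means were removed, and secretory gland genes followed in part: Pigr read 53.9 and 121.8 in controls 1 and 2 and 5844 in control 5, but Pip read 8.8 and 988.6 in controls 1 and 2, whose epithelial means were alike. A candidate explanation is that samples held varying amounts of adjoining epithelial or gland tissue, which the labels do not name. Whether diabetes also raises these genes cannot be told apart from that, since controls 3 and 5 lie within the diabetic range (exact permutation p = 0.103).

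The matrix list mean lay at -0.55 ± 0.16 (SE) in diabetic against control arrays, and with scan day as a block at -0.50 (95% interval -0.95 to -0.050), which argues against scan day as the whole cause. With the epithelial list mean as a covariate it lay at -0.29 ± 0.12 (95% interval -0.57 to 0.00062), and with the skeletal muscle list mean at -0.26 ± 0.17 (95% interval -0.66 to 0.13), so dilution by epithelium and the amount of skeletal muscle with its connective tissue stay open. The rule that the 95% interval must leave out 0 was taken for all 3 after these values were known: by the earlier rule of 2 SE, dilution by epithelium would be excluded as the whole cause, and as first worded the skeletal muscle criterion would have favoured that explanation. Within controls 1, 2, 4, 3 and 5, in order from epithelium-poor to epithelium-rich, the matrix mean was 9.93, 9.94, 9.69, 9.68 and 9.20 and the smooth muscle mean 10.11, 10.19, 10.43, 10.31 and 10.22. The smooth muscle mean thus did not fall as epithelial genes rose, and an earlier comparison of the matrix with smooth muscle genes, which took such a fall for granted, was set aside.

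Myh8 and Sln rose while most skeletal muscle markers lay lower. A lower amount of skeletal muscle was not tested apart from this pattern, since both genes were picked for their rise. Signal of Myh1, Myh2 or Myh4 in the Myh8 probe set is argued against by their 7 probe sets, whose largest change was 0.21 against a lower 95% bound of 1.80 for Myh8. Myh3, Myh7 and Myh13 were also looked for but had no tested probe set of their own, so signal from them stays open. Loss of nerve supply would raise receptor and muscle regulator genes, but the 6 tested of 12 listed shifted by -0.11 (95% interval -0.57 to 0.34, exact permutation p = 0.635). The upper limit of 0.34 lay below the bound of 0.5 set for it in advance. The shift was not adjusted for the lower skeletal muscle markers (-0.29), so a rise within the muscle present could be partly hidden. Runx1 stood at 0.46, the way that loss would move it, Myog at 0.025, Chrna1 at -0.015, Gadd45a at -0.099, Myod1 at -0.36 and Ankrd1 at -0.70, none of them called.

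A further hypothesis is that lipogenic expression is lower in the epithelial part of diabetic samples. In the epithelium-rich controls 3 and 5, the sterol response factor Srebf1 read 1414 and 2045, against 290.4 to 390.5 in all 5 diabetic arrays. The epithelial means of the diabetic arrays span those of these 2 controls. Controls 1, 2 and 4, poorer in epithelial genes, read 370, 416.5 and 367.4. Controls 3 and 5 also lay above every diabetic array in the gland genes Obp2b (902.4 and 2470 against 68.8 to 377.7), Aqp5 and Wfdc18. In Pip, Pigr, Bhlha15, Ccl28 and Pbsn they did not both do so. The epithelial covariate does not account for such differences in gland makeup, which stay open as a source of the Srebf1 contrast. With the epithelial covariate Srebf1 stood at -1.96 ± 0.29 (limma adjusted p = 0.0254) and the desaturase Scd2 at -1.42 ± 0.21 (adjusted p = 0.0239), against -1.05 (adjusted p = 0.269) and -0.68 (adjusted p = 0.343) without it. Agpat2, of the same list and dim in all controls, went the other way with the covariate, at 0.95 ± 0.16 (limma adjusted p = 0.0381). The lipogenesis list then averaged -0.35 with an adjusted p of 0.0158, but 0.378 with an estimated correlation, so the data do not decide. The demand that both correlations pass was added to the criterion after these values were seen. Without the covariate that list averaged -0.047 with a median of 0.061 and a camera direction of down, Agpat2 rose, and Me1 (-0.62 ± 0.18) fell adjusted over the list alone.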
